A study of Populus alba x Populus glandulosa with 9 samples.

How the data were processed

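RNA sequencing was carried out on stems of 84K poplar, a hybrid of Populus alba and Populus glandulosa grown widely as a laboratory tree. The 9 libraries came from wild-type plants aged 6 months and about 200 cm tall. Per the labels, 3 libraries were made from internodes 2 to 3 (top), 3 from internodes 9 to 10 (middle) and 3 from internodes 14 to 15 (bottom). Poly(A) RNA was isolated with oligo(dT) beads, made into libraries and sequenced as paired-end reads, per the labels' protocols. The labels do not say whether libraries of 1 position came from separate plants. All p-values therefore measure the spread between these libraries, which may be partly technical.

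The read trimmer Trimmomatic 0.36 and the aligner HISAT2 are named in the submitters' processing notes. The version of the aligner, the counting program, the genome build, the annotation and the strand setting are not given in the sources used here. The deposited count table holds whole-number read counts for 85755 gene identifiers, with 1 column per library. Every entry in it was even: of 503602 entries above 0, 0 were odd. Such a table would result from counting both mates of each read pair, and read pairs are given here as counts divided by 2. The deposited FPKM table holds the authors' values scaled to gene length and library total. Counts and FPKM were above 0 in the same entries. The gene length implied by their ratio differed between libraries by at most 0.152% over the 46160 genes where it could be computed. Each column was matched to its library by the code in the sample title, and 0 columns belonged to other samples.

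Total counts ranged from 41434042 to 75217046 per library, and each read pair is taken here to stand for 2 of them. The identifiers are of 3 kinds: 38368 have the letter A and a number after the prefix, 38471 have G and a number, and 8916 have Un. The files do not pair identifiers with gene names or positions, and no genome or annotation was used here. Genes are therefore given by identifier, A, G and Un are used only as classes of identifier, and no function is given for any gene. For the same reason, reads shared between near-identical copies, overlapping genes or antisense genes could not be examined gene by gene. The 32 gene lists fixed in advance by product name could not be matched, so the set tests planned for them were not run.

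Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 52436 genes. The kept genes held over 99.8% of the counts of every library. Libraries were scaled by TMM, and 1 quasi-likelihood model with a coefficient per position was fitted to all 9 libraries. The contrasts were middle against top, bottom against middle and bottom against top. An F test over the 3 positions and a test of the difference between the 2 steps down the stem came from the same fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Genes called in the F test were also sorted by their calls in the 2 steps.

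The genes named in the text follow a rule set before the data were examined, in the form it gives for identifiers without product names. For each comparison it took the 2 largest rises and the 2 largest falls in log2 fold change. It considered called genes with a mean of at least 5 FPKM in the higher position and no overlap between the 2 positions, which chance gives for 10% of genes with 3 libraries against 3. Where all 3 libraries of a position had 0 counts, the fold is given as a bound computed against 3 read pairs over the group. Where the lower position held few read pairs, the ratio of pooled read pairs is given with its exact 95% binomial interval. Such bounds and intervals cover counting error only. Where the median change of a list is given, it was also computed with genes at 0 counts set to their bound. Shares of counts per identifier class were compared with exact two-sided permutation tests, which cannot go below p = 0.1 for 3 libraries against 3.

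Replicates were compared before averaging. Read pairs of libraries of 1 position differed far beyond sampling noise, with a chi-square per degree of freedom of 21.8 to 53.4, so all 9 libraries were kept as separate samples.

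The pipeline was tested on simulated read pairs, doubled as in the deposited table, drawn from the real means, dispersions and library sizes with 200 genes changed. In the simulation of middle against top, 49957 genes were run. The edgeR test recovered 6% of the 2-fold and 63% of the 4-fold changes, and 4.17% of its calls were false. In the simulation of bottom against middle, 49949 genes were run, with 7% and 68% recovered and 2.6% false. In that of bottom against top, 49955 genes were run, with 6% and 53% recovered and 6.35% false. It changed the bottom libraries alone, as did that of bottom against middle. The test of the difference between steps recovered 0% of 2-fold and 4-fold changes in the simulation of middle against top. In a further simulation of that step with 49956 genes it recovered 61% of 16-fold and 67% of 64-fold changes. All these shares hold for 200 changed genes. Where far more genes change, recovery at the same threshold can differ.

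Alternatives set before the data were examined were other scalings (RLE, upper quartile), other filters, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) or log2(FPKM + 0.1), a replicate block, a fold minimum, 2-group fits and leaving out libraries. Halving the counts to read pairs and thinning all libraries to the lowest total were added after the data were seen. For the limma fits the fold change is on the log2(FPKM + pseudocount) scale, which understates changes of low genes.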

Results

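Gene expression was measured along the stem of 84K poplar at 3 positions: internodes 2 to 3 (top), 9 to 10 (middle) and 14 to 15 (bottom), with 3 libraries each. Each library held 41434042 to 75217046 counts, with a count for 55282 to 56870 of the 85755 gene identifiers. The most abundant gene took at most 0.31% of a library, and the 20 most abundant genes took 2.19% to 3.39%. A count of 0 in a library allowed an FPKM of up to 0.0798 to 0.145 for a gene of 1 kb, set by 3 read pairs and covering counting error only.

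The 3 top libraries were separated from the other 6 along the first principal component of log2 CPM, which held 50.6% of the variance. Along the second component, with 15.7% of the variance, the middle libraries lay above the bottom libraries. Middle library 2 was at a score of 165.5 on this axis, against 56.95 and 13.7 for the other middle libraries, and at -3.606 on the first component, against 67.49 and 76.02. Correlations of log2 CPM were 0.918 to 0.96 between libraries of 1 position and 0.791 to 0.954 between libraries of different positions. Of the 52436 genes tested, 11599 (22.1%) differed between positions in the F test of edgeR's quasi-likelihood model at an adjusted p under 0.05. This count was 6621 without top library 2, 6835 without top library 3 and 7671 without bottom library 2. It was 6724, 3698 and 422 without replicate number 1, 2 or 3 in all positions, and 18006 in DESeq2.

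**Figure D1:**
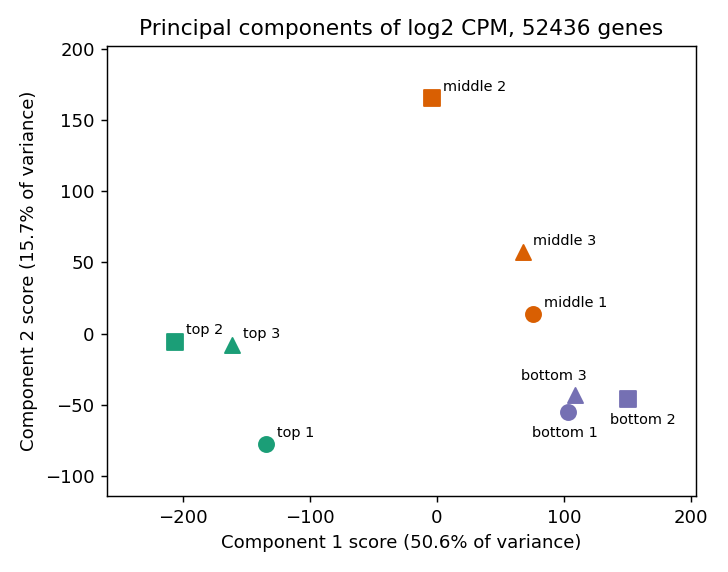
Scores of the 9 libraries on the first and second principal components of log2 CPM over 52436 genes, with colour for position and marker shape for library number. The top libraries sit at -134.6 or below on component 1 (50.6% of variance), and middle library 2 has the highest score on component 2 (165.5).

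The first comparison asked which genes differ between the upper stem and its middle part. From top to middle, 4301 genes rose and 5478 fell, together 18.6% of the genes tested. The median log2 fold change was 1.45 for the rises, with quartiles of 0.87 and 2.498, and -0.95 for the falls, with quartiles of -1.43 and -0.68. Setting genes with 0 counts in the lower position to their bound left these medians as they were. At least a 2-fold change was seen in 2932 of the genes that rose and 2580 of those that fell. The genes that rose had a median of 2.63 FPKM in the top and 7.50 in the middle, and the genes that fell went from 15.9 to 8.48 FPKM. Among the 500 most abundant genes, 50 rose, 112 fell and 338 were not called.

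The largest fitted rise between top and middle was that of Pop_A06G053506. It had 0 counts in all 3 top libraries and 12.3 ± 3.85 FPKM in the middle (SD, n = 3), at least 670-fold higher, with an adjusted p of 0.000726 in edgeR's quasi-likelihood test. Pop_A05G056091 was likewise at 0 counts in the top and at 6.90 ± 3.51 FPKM in the middle (SD, n = 3), at least 273-fold higher, with an edgeR adjusted p of 0.00406. The largest fitted falls were those of Pop_G17G081536 and Pop_G05G032865, both at 0 counts in all 3 middle libraries. Fitted values at 0 counts depend on the prior count, so they do not rank the measured ratios. Pop_A03G049884, for example, went from 12.9 ± 14.6 FPKM in the top to 0.01 ± 0.02 in the middle (SD, n = 3). Pop_G17G081536 had 6.46 ± 4.71 FPKM in the top (SD, n = 3), so it was at least 75.9-fold lower in the middle (edgeR adjusted p = 0.0121). In the bottom libraries it was measured again at 3.04 ± 2.92 FPKM (SD, n = 3). Pop_G05G032865 had 6.51 ± 2.33 FPKM in the top and was at least 73.9-fold lower in the middle (edgeR adjusted p = 0.00588, SD over n = 3). In total, 93 of the genes that rose had 0 counts in all top libraries, and 40 of those that fell had 0 counts in all middle libraries.

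The number of genes called was 6500 without top library 2 and 5858 without middle library 3. It was 4731, 3621 and 322 without replicate number 1, 2 or 3 in all positions, and the 322 were 207 rises and 115 falls. Leaving 1 replicate number out of all positions ended the calls of Pop_G17G081536 without number 1 or 3 (edgeR adjusted p = 0.0534 and 0.131) and of Pop_G05G032865 without number 3 (edgeR adjusted p = 0.0712), within ranges over all alternatives of 8.24e-09 to 0.131 and 3.55e-10 to 0.0712.

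**Figure D2:**
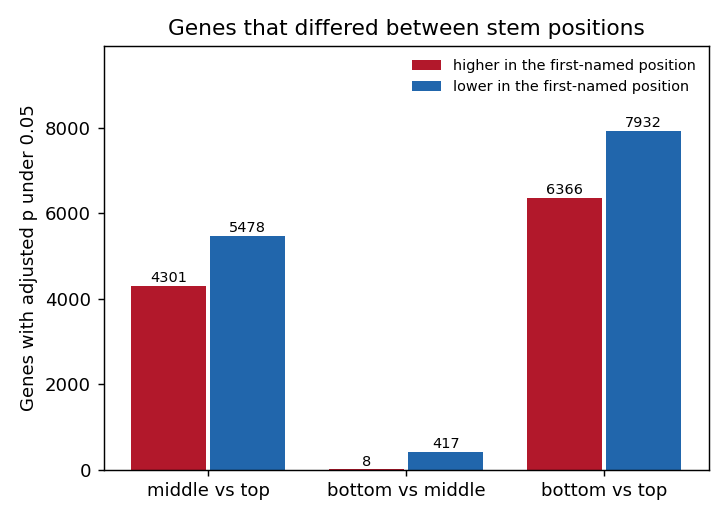
Number of genes with an edgeR adjusted p under 0.05 in each comparison, with bars for genes higher (red) and lower (blue) in the first-named position. Between middle and bottom, 8 genes were higher and 417 lower in the bottom, against 4301 or more in each direction for both comparisons with the top.

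The second comparison covered the step from the middle to the bottom of the stem. Here 8 genes rose and 417 fell, which is 0.81% of the genes tested. The genes that fell had a median log2 fold change of -3.40 with quartiles of -4.82 and -2.29, and 412 of the 417 fell at least 2-fold. Smaller falls could seldom be called: in the simulation of this step, 7% of 2-fold and 68% of 4-fold changes were recovered. The median change therefore depends on the threshold. It is not comparable with that of the first step, where far more genes were called. The median level of the 417 genes was 22.4 FPKM in the top, 32.4 in the middle and 2.96 in the bottom. Within the positions, their median was 19.2 to 24 FPKM over the top libraries, 17.2 to 46.7 over the middle libraries and 2.24 to 3.15 over the bottom libraries. The highest of these middle values was that of middle library 2.

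Among the genes that fell, Pop_G06G003287 and Pop_G01G004462 had the largest fitted changes. Pop_G01G004462 went from 62.99 ± 76.5 FPKM in the middle to 0.11 ± 0.11 in the bottom (SD, n = 3, edgeR adjusted p = 0.0255). Its pooled read pairs were 556-fold lower (95% interval 302 to 1160), with 27.7, 150.8 and 10.5 FPKM in the 3 middle libraries. Pop_G06G003287 went from 6.89 ± 9.22 FPKM to 1 read pair in the 3 bottom libraries together (SD, n = 3, edgeR adjusted p = 0.0447), a pooled ratio of 916 (95% interval 164 to 36200). Its middle libraries held 0.83, 17.5 and 2.33 FPKM, so its mean there rested mainly on middle library 2.

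The 2 largest rises between middle and bottom were those of Pop_A04G070603 and Pop_G04G060295. Pop_A04G070603 had 4.79 ± 2.55 FPKM in the top, 0.10 ± 0.08 in the middle and 5.43 ± 2.69 in the bottom (SD, n = 3, edgeR adjusted p = 0.0249 for the last step). The middle value rests on 2 read pairs, and the pooled ratio of bottom to middle was 53.0 (95% interval 14.4 to 442). Pop_G04G060295 had 11.5 ± 6.16, 1.58 ± 0.14 and 20.04 ± 12.5 FPKM (SD, n = 3), a log2 fold change of 3.62 with a standard error of 0.59 for the last step (edgeR adjusted p = 0.0315). Of the 8 genes that rose, 7 had fallen between top and middle.

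At an unadjusted p under 0.05, 897 genes were higher and 3393 lower in the bottom than in the middle in edgeR, and 1631 and 2368 in limma on log2(FPKM + 1). Without bottom library 1, 2 or 3, edgeR called 15, 1 and 0 genes, and without top library 2 or 3 it called 272 and 225. All 417 genes stayed lower at an unadjusted edgeR p under 0.05 in these fits. Their median log2 fold change was -3.55, -3.27 and -3.43 without bottom library 1, 2 or 3. They were chosen with all 9 libraries, so this is no separate test. At an unadjusted p under 0.05, 891 genes were higher and 2766 lower without bottom library 3. Without middle library 2, 3 genes rose and 345 fell. Without replicate number 1, 2 or 3 in all positions, 263, 73 and 0 genes were called. The 4 named genes lost their calls whenever 1 replicate number was left out of all positions (edgeR adjusted p = 0.0635 to 0.485), and over all alternatives their adjusted p ranged from 1.03e-09 in DESeq2 to 0.485. Pop_G06G003287 also lost its call on counts halved to read pairs (edgeR adjusted p = 0.0556) and in limma on log2(FPKM + 1) (limma adjusted p = 0.426).

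**Figure D3:**
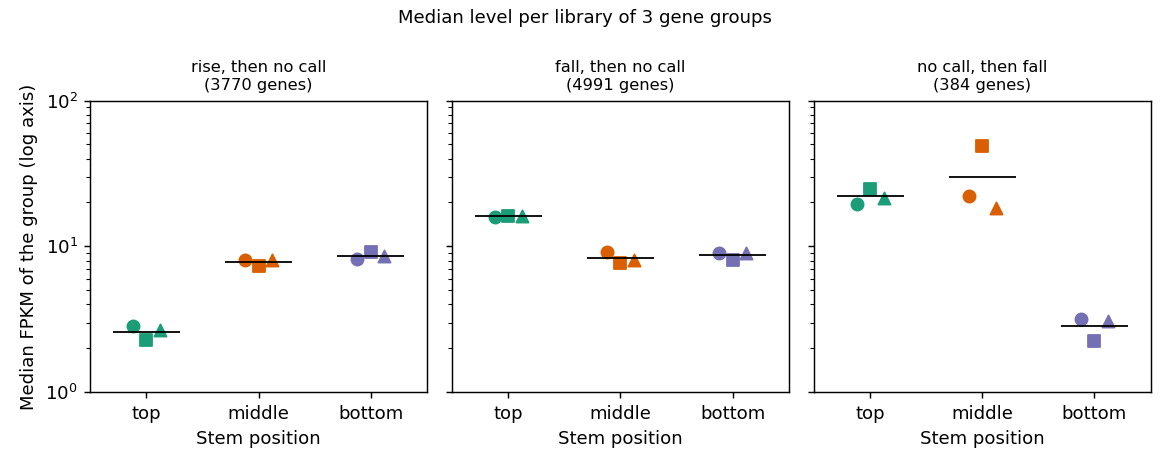
Median FPKM per library (log axis) of the 3 largest gene groups with a call from top to middle or from middle to bottom. Each point is 1 library, with marker shape for library number and lines at the mean of the 3 medians. The 2413 genes of the F test with no call in either step are not shown. The groups were chosen on these same libraries. The third group (384 genes) lies between 2.25 and 3.16 FPKM in the bottom libraries and at 18.3 or above in all others.

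The third comparison set the 2 ends of the stem series against each other. From top to bottom, 6366 genes rose and 7932 fell, 27.3% of the genes tested. Which direction held more genes depended on the method: limma called 7416 rises and 6681 falls on log2(FPKM + 1), and edgeR with upper quartile scaling called 7059 and 7168. The median log2 fold change was 1.27 for the genes that rose and -1.13 for those that fell, and 3912 and 4528 of them changed at least 2-fold. The genes that rose went from a median of 3.58 FPKM in the top to 9.14 in the bottom. Those that fell went from 14.1 to 6.31 FPKM. Among the 500 most abundant genes, 78 rose and 145 fell. Among the 100 most abundant, 18 rose and 19 fell.

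Pop_A06G053506 and Pop_A05G056091, at 0 counts in the top, again had the largest fitted rises. They reached 17.9 ± 6.21 and 12.6 ± 10.8 FPKM in the bottom (SD, n = 3), at least 976-fold and 521-fold higher than the top (edgeR adjusted p = 0.000446 and 0.00225). In Pop_A05G056091, bottom library 2 was highest, with 24.6 FPKM, against 9.60 and 3.68 in the other bottom libraries. The largest fitted falls were those of Pop_G03G010555 and Pop_A03G049884. Both had 0 counts in all 3 bottom libraries and 13.8 ± 16.0 and 12.9 ± 14.6 FPKM in the top (SD, n = 3). They were at least 450-fold and 383-fold lower in the bottom (edgeR adjusted p = 0.00531 and 0.00348). In both, top library 1 was highest, with 32.2 and 29.7 FPKM, against 3.23 to 5.68 FPKM in the other top libraries. Each was also near 0 in the middle, at 0.05 ± 0.08 and 0.01 ± 0.02 FPKM (SD, n = 3). Without replicate number 3 in all positions both lost their calls (edgeR adjusted p = 0.0572 and 0.0501), within ranges over all alternatives of 7.08e-05 to 0.0572 and 1.71e-07 to 0.0501. The number of genes called was 9525 without top library 2, 7997 without bottom library 2, and 5675 and 2898 without replicate number 2 or 3 in all positions.

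**Figure D4:**
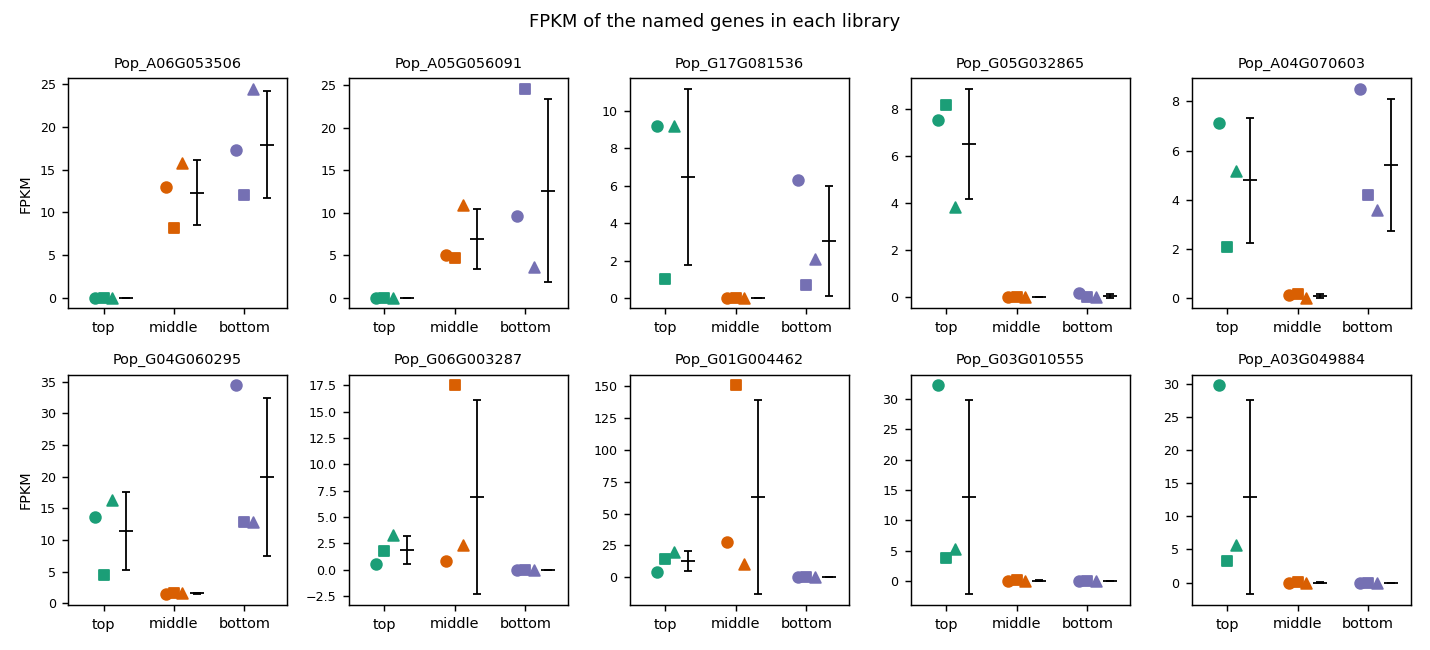
FPKM of the 10 named genes in each library by stem position, with marker shape for library number and a black bar for the mean and SD of 3 libraries. Pop_A06G053506 and Pop_A05G056091 are at 0 in all top libraries, and the middle values of Pop_G06G003287 and Pop_G01G004462 are highest in middle library 2.

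Sorting the 11599 genes of the F test by their calls in the 2 steps gave 3 main groups with a call in at least 1 step. The first held 3770 genes that rose from top to middle with no call afterwards, at median levels of 2.69, 7.94 and 8.80 FPKM in top, middle and bottom. The second held 4991 genes that fell from top to middle with no call afterwards, at 16.1, 8.43 and 8.85 FPKM. The third held 384 genes with no call in the first step that fell in the second, at 23.1, 34.2 and 3.01 FPKM. The direct test of the difference between the steps called 330, 160 and 188 genes of these groups. A call in 1 step alone thus does not show that the steps differ. Without replicate number 3 in all positions the groups held 155, 107 and 0 genes, and DESeq2 gave 6390, 6617 and 1382. A further 2413 of the 11599 genes, more than in the third group, had no call in either step. Of these, 774 were called higher and 1488 lower in the bottom than in the top. Only 1 gene, at 6.72, 5.32 and 10 FPKM, rose in the second step alone.

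Of the genes called in both steps, 21 rose and then fell, 7 fell and then rose and 12 fell in both. Independent lists of these sizes would share 34.2, 0.84 and 43.6 genes. Both steps use the same middle libraries, which by itself gives log2 fold changes of the 2 steps a correlation of -0.51 across genes in simulated unchanged libraries. The observed correlation across genes, which are not independent replicates, was -0.065. The covariance was -0.072 against -0.14 in the simulation. Genes called in both steps numbered 0 on average over 10 simulations. Since no gene was changed in them, this 0 gives no expected number of shared calls among genes that do change.

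Most calls from top to middle were also calls from top to bottom in the same direction, 3793 of 4301 rises and 4735 of 5478 falls. Independent lists would share 522 and 829 genes. Of the 417 genes that fell from middle to bottom, 407 were also lower in the bottom than in the top, against 63.1 for independent lists. Part of these overlaps may come from the libraries the comparisons share, since 3 libraries are too few to split. In simulated unchanged libraries the shared group gave a covariance of 0.135 between middle against top and bottom against top, where 1.31 was observed. For bottom against middle and bottom against top, it was 0.137 simulated and 0.809 observed.

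The difference between the 2 steps was tested directly. It passed the threshold in 708 genes, of which 541 had the lower change in the second step and 167 the higher. DESeq2 gave 2670 and 2090 genes and limma on log2(FPKM + 1) gave 208 and 159. With the top libraries kept, 8 of the 20 ways of assigning the other 6 libraries to middle and bottom gave at least 708 genes, the real one included. The 541 genes had medians of 3.09, 15.9 and 5.46 FPKM in top, middle and bottom, and the 167 genes had 26.0, 6.98 and 9.44 FPKM. Leaving out 1 library gave 25 to 482 such genes, lowest without bottom library 1 and highest without top library 1. It gave 41 and 60 without bottom libraries 2 and 3, 426, 261 and 321 without middle libraries 1, 2 and 3, and 227 and 306 without top libraries 2 and 3. Without replicate number 1, 2 or 3 in all positions, 0, 76 and 1 genes had differing steps.

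Identifiers of class A and class G took nearly equal parts of the counts at each position. Class A held 50.13 ± 0.14% in the top, 50.33 ± 0.07% in the middle and 50.21 ± 0.09% in the bottom (SD, n = 3). Class G held 48.53 ± 0.18%, 48.35 ± 0.07% and 48.48 ± 0.06% (SD, n = 3), and class Un 1.34 ± 0.05%, 1.32 ± 0.01% and 1.31 ± 0.03% (SD, n = 3). The share of class A was 0.197 percentage points higher in the middle than in the top. The exact two-sided permutation p was 0.2 to 0.8 over the 9 tests of the 3 classes, where 0.1 is the smallest that 3 libraries against 3 allow.

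Genes of class A and class G were also called at like rates. From top to bottom, 12.22% of the 25901 tested class A genes and 12.15% of the 25505 class G genes rose, and 15.0% and 15.4% fell. From middle to bottom, 194 class A and 220 class G genes fell. Fisher's exact tests of class A against class G gave Benjamini-Hochberg adjusted p-values of 0.669 to 0.808 over 6 tests across genes, which are not independent replicates.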

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

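The tests of middle library 2 as a top library under a wrong label and as a mixture, the test without middle library 2 and the assignments with the top libraries kept were chosen only after the results were seen.

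The 2 steps down the stem differed in 708 genes, by a direct test of the difference in edgeR's model. Among the named genes, the second step was lower than the first by a fitted log2 value of -12.7 in Pop_A06G053506, -11.1 in Pop_A05G056091, -11.6 in Pop_G06G003287 and -11.5 in Pop_G01G004462. It was higher by 11.1 in Pop_A04G070603 and by 6.5 in Pop_G04G060295. For Pop_A06G053506 and Pop_A05G056091, at 0 counts in the top, these fitted values depend on the prior count and are no bounds. The edgeR adjusted p of the 6 differences was 0.0108 to 0.05. Of 100 drawn splits of the 9 libraries into 3 groups of 3, 3 gave at least 708 genes, the real one included. The number of genes depends on which group takes the middle role, not only on the grouping. The real grouping with middle and bottom swapped was not among the draws, and it gave 4253 genes. The share of 3 in 100 therefore does not exclude chance. The highest other drawn split gave 14252 genes, with the 3 top libraries together in the middle role. This points to the separation of the top libraries. The remaining drawn split of the 3, with 947 genes, parted them. With the top libraries kept, 8 of the 20 assignments of the other 6 libraries to middle and bottom gave at least 708 genes, the real one included. The highest was 4253, with middle and bottom swapped, and the 18 mixed assignments gave 145 to 3076. Chance in the assignment of the middle and bottom libraries can therefore not be excluded as a source of the number of these genes.

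The same draws bear on the F test over positions. The real split called 11599 genes and was the only 1 of the 100 to reach that number. Taking the libraries as independent samples, a random grouping of all of them can therefore be excluded for this test. A chance assignment of the middle and bottom libraries cannot, since too few draws kept the top libraries together. The highest other split called 9997. All 4 drawn splits that kept the top libraries together called at least 8690 genes, and none of the others called more than 977. For the pairwise comparisons, 1 of 10 splits of the 6 libraries, the real one, gave as many calls. These splits are too few for a share under 0.05. The real counts were 9779, 425 and 14298 for middle against top, bottom against middle and bottom against top, and the highest other split called 0 in each.

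Middle library 2 was at least 2-fold above all 8 other libraries in 1087 genes, against 620 in bottom library 2 and at most 278 in any other library. In the other direction top library 2 stood furthest apart, at least 2-fold below all 8 others in 1571 genes, against 685 in top library 1 and 221 in middle library 2. For the 1087 genes the tables argue against depth, since after thinning every library to the lowest total their number was at least 1.76 times that of the next library in each of 5 draws, and against a top library under a middle label, since its lowest correlation with a middle library exceeded its highest with a top library by 0.04. A mixture with material like that of the top libraries stays open: the 1087 genes are the pattern itself and test nothing further, and over 8246 genes called at least 2-fold different between top and bottom in a fit without the middle libraries, this library lay at a median of 0.751 of the way, with a lower quartile of 0.318, against 0.835 and 0.861, with 0.639 and 0.574, in the other middle libraries. A difference in plant, tissue content or handling stays open, and no biological explanation was tested.

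Nearly all called changes from middle to bottom were falls, 417 of 425. The tables argue against library scaling, since the share of falls was at least 98.07% under both other scalings, and against unequal depth, since at least 399 genes fell in each of 3 draws thinned to the lowest total. They argue against middle library 2 alone, since 345 genes fell without it. The number of calls did depend on each bottom library: 15, 1 and 0 genes were called without bottom library 1, 2 or 3. The position on the stem, which the design names, stays open as untested apart from other differences between these libraries. As a hypothesis found on the same data, these genes may be active in the upper and middle internodes and turned down in the bottom ones.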

How the results depend on the processing

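Halving and thinning of the counts were chosen after seeing the data. Under RLE or upper quartile scaling, both other count filters, thinning and halving, the total number of called genes stayed within 1.5 times its value in each comparison, the F test and the test of differing steps. The 8 rises from middle to bottom became 14 without a count filter. The gene patterns were not counted under upper quartile scaling, other filters, thinning or halving, and depth limits the folds of genes at 0 counts, given as bounds. DESeq2 called 1768 genes from middle to bottom, 18006 over all positions and 4760 with differing steps. It gave 6390 genes with a rise and then no call, 1382 with a fall in the second step alone and 328 called in both steps. In simulations with 200 changed genes, 47.3% of its calls in bottom against middle were false when that step was simulated, 57% to 59.6% of those over all positions and 61.2% to 66.2% of those with differing steps, at 2-fold and 4-fold changes. These shares stood for 114, 172 to 202 and 90 to 96 false calls. They are set by how few genes were changed, so they do not give the false share of the real DESeq2 calls. limma on log2(FPKM + 1) called 367 genes with differing steps, 398 at a mean of at least 1 FPKM, and 98 unfiltered, where it also called 165 genes from middle to bottom. A 1.5-fold threshold (glmTreat) left 2880, 272 and 5411 genes for middle against top, bottom against middle and bottom against top. A log2 fold change of at least 1 left 5512 and 8440 genes for the comparisons with the top and 2485 genes with a fall and then no call. Fits of only the 2 groups compared called 6393 genes for middle against top and 103 for bottom against middle, with fewer libraries to estimate the spread. A replicate block lowered the genes with differing steps to 377 and raised the rises from middle to bottom from 8 to 15, and moved no other total by over 1.5 times. It called 8802, 423 and 13392 genes in the 3 comparisons. Deviations from the position means correlated with r from -0.1561 to 0.2699 between same-numbered libraries, over 0.1 in all 3 pairs of top and middle but in only 4 of all 9 pairs, so the numbers were not taken to pair the samples. Of the 9 libraries, 7 correlated best with one of their own number, a hint from the data, not a stated design. The codes in the sample titles also share a letter within a replicate number (PAS, PBS and PCS), but the labels do not say what it marks.

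Leaving out 1 library or 1 replicate number gave 322 to 9187 genes for middle against top, 0 to 563 for bottom against middle, 2898 to 15009 for bottom against top, 422 to 11194 over all positions and 0 to 482 with differing steps. The lowest values came without replicate 3, except that no gene had differing steps without replicate 1. Without 1 replicate number, the patterns held 155 to 2037 genes with a rise and no further call, 107 to 2259 with a fall and no further call, 0 to 237 with a fall in the second step alone and 0 to 26 called in both steps. These fits have fewer samples. The class A share by summed FPKM was 49.278%, 49.503% and 49.472% in top, middle and bottom. Without the 20 most abundant genes it was 50.367%, 50.419% and 50.299%. The named genes kept their direction in all 84 alternative values, and 19 of these no longer passed the threshold. Except where fewer samples or a stricter threshold account for a change by construction, the cause was not tested. Other settings of the gene list tests were not run, since the lists could not be matched.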

Other observations

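The counts of genes at 0 in 1 position and the comparisons of identifier numbers, gene lengths and neighbouring table entries were chosen only after the data were seen, and the matching of class A and class G identifiers by expression only after matching by length had been run. Tests of the class A share of reads, and of a change in the ratio of class A to class G between positions, were first run on the pairs matched by length, and were left out once those pairs were no longer taken as copies.

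Some genes were listed at 0 counts in all 3 libraries of 1 position and at 1 FPKM or more in all 3 of another. There were 29 such genes at 0 in the bottom and measured in the top, and 22 at 0 in the top and measured in the bottom. Between top and middle, 20 were at 0 in the top and 3 at 0 in the middle. Between middle and bottom, 2 were at 0 in the bottom and measured in the middle. Other splits of the same 6 libraries gave at most 1 such gene in each of the 6 comparisons.

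Calls were also counted by the number that follows the letter in the identifier, with Fisher's exact test over 234 combinations of class, comparison and direction. Genes are not independent replicates. Identifiers with number 11 rose more often from top to bottom than other genes in both letter classes. In class A11, 153 of 970 genes rose (15.8%, against 12.1% of all others, Benjamini-Hochberg adjusted p = 0.0379). In class G11, 77 of 427 rose (18.0%, against 12.1%, adjusted p = 0.0342). In class G06, 31 of 1966 genes fell from middle to bottom (1.58%, against 0.765%, adjusted p = 0.0342), but under DESeq2 calls the rates were 3.51% and 3.15%. Identifiers of class Un fell less often from top to bottom, 112 of 1030 (10.9%, against 15.2%, adjusted p = 0.0175), and from top to middle, 76 of 1030 (7.38%, against 10.5%, adjusted p = 0.0379). Their rates of rises were also lower but did not pass the threshold, 10% against 12.18% from top to bottom and 7.09% against 8.22% from top to middle (adjusted p = 0.384 and 0.92). The lower rate may thus not be particular to falls.

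The median length implied by counts and FPKM was 1303 nt for falls and 1660 nt for rises from top to middle, and 1390 and 1631 nt from top to bottom, against 1595 nt for the genes not called in each of these comparisons. From middle to bottom it was 1158 nt for falls and 1568 nt for genes not called.

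Entries that neighbour each other in the deposited tables within 1 identifier class changed alike. Over 39475 neighbouring pairs, Spearman's rho of their log2 fold changes was 0.128, 0.14 and 0.146 for middle against top, bottom against middle and bottom against top. In 100 shuffles within classes it stayed between -0.0174 and 0.0163. Genes are not independent replicates, and whether table neighbours are neighbours in the genome was not examined.

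The hypothesis was tested that class A and class G identifiers with the same number hold corresponding gene copies. Over 3101 pairs with the same number and equal implied length, Spearman's rho of log2 fold changes across genes, which are not independent replicates, was 0.0832, 0.0393 and 0.08 for middle against top, bottom against middle and bottom against top, above the highest of 10 sets of pairs with different numbers in each (0.0363, 0.0252 and 0.037). The gap of 0.043 for bottom against top is small enough for chance length matches to account for most of these pairs.

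Of 1462 pairs of changed class A and class G genes that were each other's best-correlated partner over the 9 libraries, 19.4% had the same number, against 4.38% to 8.21% in 1000 shuffles, which argues against chance sharing of a number. The same-number pairs had a median difference in implied length of 478 nt, and 12 of 282 lay within 0.5 nt, so matching by equal length could find few of them. Random assignment of all reads between identical copies would let the class A share vary between libraries by binomial counting only. In a test chosen after the data were seen, it varied with a median chi-square per degree of freedom of 4.8 over 211 pairs, above 2 in 158 of them. The spread thus exceeded binomial counting in most of these pairs. Since few same-number pairs had equal implied lengths, the case of identical copies hardly applies to them. The test therefore does not settle how their reads were assigned. Assignment of part of the reads between similar copies stays open. Corresponding copies with like regulation may account for the pairs, as a hypothesis.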
